A study of Arabidopsis thaliana with 10 samples.

How the data were processed

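RNA was measured in whole Arabidopsis thaliana Columbia seedlings grown in darkness, with 20 µg of total RNA per library. Per the labels, seeds received 3 h of white light and a 15 min far-red pulse and were then kept for 48 h in the dark at 21 °C. There were 10 genotypes with 3 biological replicates each, and the groups were taken from the labels: WT, pif1, pif3, pif4, pif5, pif345, pif145, pif135, pif134 and pifq. The labels mention technical duplicate runs, but each replicate has 1 column of values, so these runs could not be looked at separately. Libraries of different replicates were separate: their counts differed by more than counting error, with chi-square over degrees of freedom from 27.1 to 198. In all comparisons of a triple mutant or pifq with WT the libraries labelled pif134 were kept under their label.

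Per the labels, the authors captured 3′ ends in a directional library and aligned reads with Bowtie 0.12.7 to TAIR10, and the deposited values are raw read counts per locus for each replicate. The counting tool and the treatment of reads with several hits are not stated, and edgeR is named without a version or a role. In the columns of WT B, pif3 B and pif5 C an unnamed last value was not a whole number, so these deposited columns were classed as estimated counts, also called expected counts. Rounding to whole numbers was not needed, since 100% of the named values were whole numbers, and all columns were then treated alike. The unnamed last value of each column lay within 0.0665% of that column's 75th percentile, held at most 0.0015% of the total, and was left out. No organelle-encoded locus (0) was present. Of the loci, 32834 matched the TAIR10.1 reference by locus tag, and coordinates come from it. It calls PIF1 and PIF5 by their other names PIL5 and PIL6.

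Depth ranged from 18.97 M counts in pif134 C to 70.8 M in pif3 A. Factors from edgeR's TMM scaling ranged from 0.779 to 1.20. Loci were tested when they passed filterByExpr with a minimum count of 10, which left 18680. All 30 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, and p was adjusted by the Benjamini-Hochberg method within each comparison. A call means an adjusted p under 0.05, and 2-fold means an absolute log2 fold change of at least 1. The comparisons were each of the 9 mutants with WT, pifq with each triple mutant, the interaction of each PIF with its background, and the tests among the 4 triple and among the 4 single mutants. An interaction compares the effect of losing a PIF in WT with its effect in the triple mutant that keeps only this PIF. The ± values are standard errors of log2 fold changes, worked back as the absolute log2 fold change over the square root of the quasi-likelihood F. They come from the joint fit and are not the spread of the 3 replicates. Log CPM used a prior count of 2.

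Before the data were examined, 20 gene lists and a list of the 4 targeted PIF genes were written. Together they had 353 members, and 353 of these were present. The 20 lists, without that of the PIF genes, were tested in 13 comparisons with camera from limma 3.58.1. This was done at a preset correlation of 0.01, and again with the correlation estimated from the data. Of 260 list tests 79 lost their call with the estimated correlation, so the report gives that p. The lists that kept a call against WT in pifq were the antenna, photosystem, Calvin cycle and shade-responsive lists. Median, mean and camera direction differed in sign only in list tests with a camera adjusted p of 0.341 or more, among them photoreceptors and light signalling in pifq (-0.02, Up, adjusted p = 0.872) and heat shock in pif3 (0.51, Down, adjusted p = 0.807). The gibberellin, brassinosteroid, ethylene, seed oil mobilisation, heat shock and reference gene lists gave camera adjusted p of 0.804, 0.158, 0.702, 0.804, 0.872 and 0.99 in pifq against WT. A further 3 lists were written after the main results were seen, and 1 of them is not reported here.

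Genes named in the text followed a rule fixed before the data were examined. The 4 PIF genes are always named. For pifq against WT the rule took the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and every mutant replicate beyond every WT replicate. For the other comparisons it took 3 of each, for interactions the 3 smallest adjusted p, and for the tests among mutants the 5 smallest. From each list it took the 3 called members with the largest change in pifq against WT (5 for the shade-responsive and light-signalling lists), or those with the smallest p. This gave 99 genes. A gene named in the text for another comparison than the one the rule took it from was chosen after its values were seen.

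Replicate letters were checked for pairing by correlating deviations from genotype means. Within the set of WT and single mutants and the set of triple mutants and pifq, 19 of 20 pairs of genotypes had all 3 same-letter correlations over 0.1, against 1 of 25 pairs between the sets. The mean same-letter correlation was 0.363 within sets and 0.0926 between them. Within sets, all 30 libraries correlated best with a library of their own letter. Since the labels give no pairing, the replicate letter was added as a block only as an alternative. The main fit leaves the variation shared by letter in its error, so its standard errors, adjusted p and counts are those of an unpaired model. Shared WT libraries make fold changes of different mutants correlate, so their correlation and covariance were set against 10 simulations of unchanged groups, which leave out the deviations that libraries of the same letter share.

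The alternatives tried were relative log expression (RLE) scaling, total counts alone, no filter on low counts, a mean of at least 5 CPM, an adjusted p under 0.01, DESeq2 1.42.0, only the compared genotypes in the fit, the replicate block, and leaving out each library in turn. Scaling by total counts alone moved the median log2 fold change of all genes to 0.14 in pif1, 0.14 in pif3, 0.19 in pif5, 0.17 in pif345, -0.13 in pif134, -0.21 for pifq against pif345 and -0.11 for pifq against pif135. RLE scaling moved no median by more than 0.1. Alternatives added after the data were seen were a replicate block within each of the 2 sets, a fit without the libraries labelled pif134, and a test among the other triple mutants.

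The procedure was tested on simulated data with planted changes. In pifq against WT, 13 of 67 changes of 2-fold, 59 of 67 of 4-fold and 64 of 66 of 8-fold were recovered, and 8 unchanged genes were called. With camera at the preset correlation a planted list was recovered (adjusted p = 7.42e-67) and 0 of 19 random lists were called. The simulated genes were drawn independently of each other, so random lists had little reason to be called. The test with an estimated correlation was not tried on simulated data. For the PIF1 interaction 2 of 67, 33 of 67 and 65 of 66 were recovered, and among the triple mutants 21 of 67, 58 of 67 and 62 of 66. Differences near 2-fold are therefore often missed by the fit without a block at this replication. The simulated libraries leave out deviations shared by letter, so they do not show what a block would recover in the real data.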

Results

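Transcript levels were measured in dark-grown seedlings of Arabidopsis thaliana, Columbia background, that lacked different combinations of the PHYTOCHROME INTERACTING FACTORS PIF1, PIF3, PIF4 and PIF5. These basic helix-loop-helix transcription factors promote growth in darkness and are removed when phytochromes are activated by light. Whole seedlings were harvested after 48 h of darkness, and 10 genotypes were sequenced: wild type (WT), the 4 single mutants, the 4 triple mutants that each keep 1 of the 4 genes, and the quadruple mutant pifq. Each genotype had 3 biological replicates, A, B and C, which gave 30 libraries. Total counts ranged from 18.97 M to 70.8 M per library with a median of 25.2 M, and 18680 loci had enough counts to be tested. The 10 most abundant loci took between 8.14% and 12.3% of the counts. The libraries fell into 2 sets by the way replicates deviated together, WT with the single mutants and the triple mutants with pifq. The labels give no batch, so comparisons of a triple mutant or pifq with WT cross these sets, and there the set and the genotype cannot be told apart. Single mutants against WT, and pifq against each triple mutant, were compared within a set.

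The PIF transcripts were examined first, because they check the genotype labels. PIF3 (AT1G09530, chromosome 1, 3075768 to 3079654 in TAIR10.1) averaged 73.8 CPM (counts scaled by library size) in WT and 1.91 in pif3, a log2 fold change of -5.28 ± 0.36 (SE, n = 3 per group, adjusted p = 2.52e-10). It was also low in pif345, pif135, the libraries labelled pif134 and pifq, at 3.88, 2.21, 5.49 and 1.93 CPM. PIF5 (AT3G59060, chromosome 3, 21827905 to 21830837) fell from 7.13 CPM in WT to 0.31 in pif5 (log2 fold change -4.58 ± 0.53, adjusted p = 1.95e-05), and lay between 0.25 and 0.47 CPM in pif345, pif145, pif135 and pifq. PIF1 (AT2G20180, chromosome 2, 8704024 to 8707009) fell from 25.0 CPM in WT to 1.61 in pif1 (-3.96 ± 0.65, adjusted p = 0.000415) and to 3.79 in pifq (-2.73 ± 0.61, adjusted p = 0.00246). It was 7.66 CPM in pif145 (adjusted p = 0.0524) and 5.71 in pif135, where replicate A held 12.4 CPM against 2.28 and 2.43 in B and C. The pif135 call (adjusted p = 0.0162) was lost without WT C, pif135 B or pif135 C.

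In the libraries labelled pif134, PIF1 was not low: the 3 replicates held 58.1, 56.7 and 74.5 CPM, a log2 fold change of 1.33 ± 0.57 against WT (adjusted p = 0.111). PIF3 was low in the same libraries, and PIF5, which this genotype should keep, was present at 19.4 CPM. PIF4 (AT2G43010, chromosome 2, 17886101 to 17889087) averaged 11.7 CPM in WT and 18.8 in pif4 (0.68 ± 0.33, adjusted p = 1.0). It was higher than in WT in pif345, pif145, pif135, the libraries labelled pif134 and pifq, with log2 fold changes of 2.23, 1.83, 2.42, 3.64 and 1.98. The library protocol reads 3′ ends, so reads from beyond a disrupted part of PIF4 remain possible, and its count does not check the pif4 label.

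**Figure D1:**
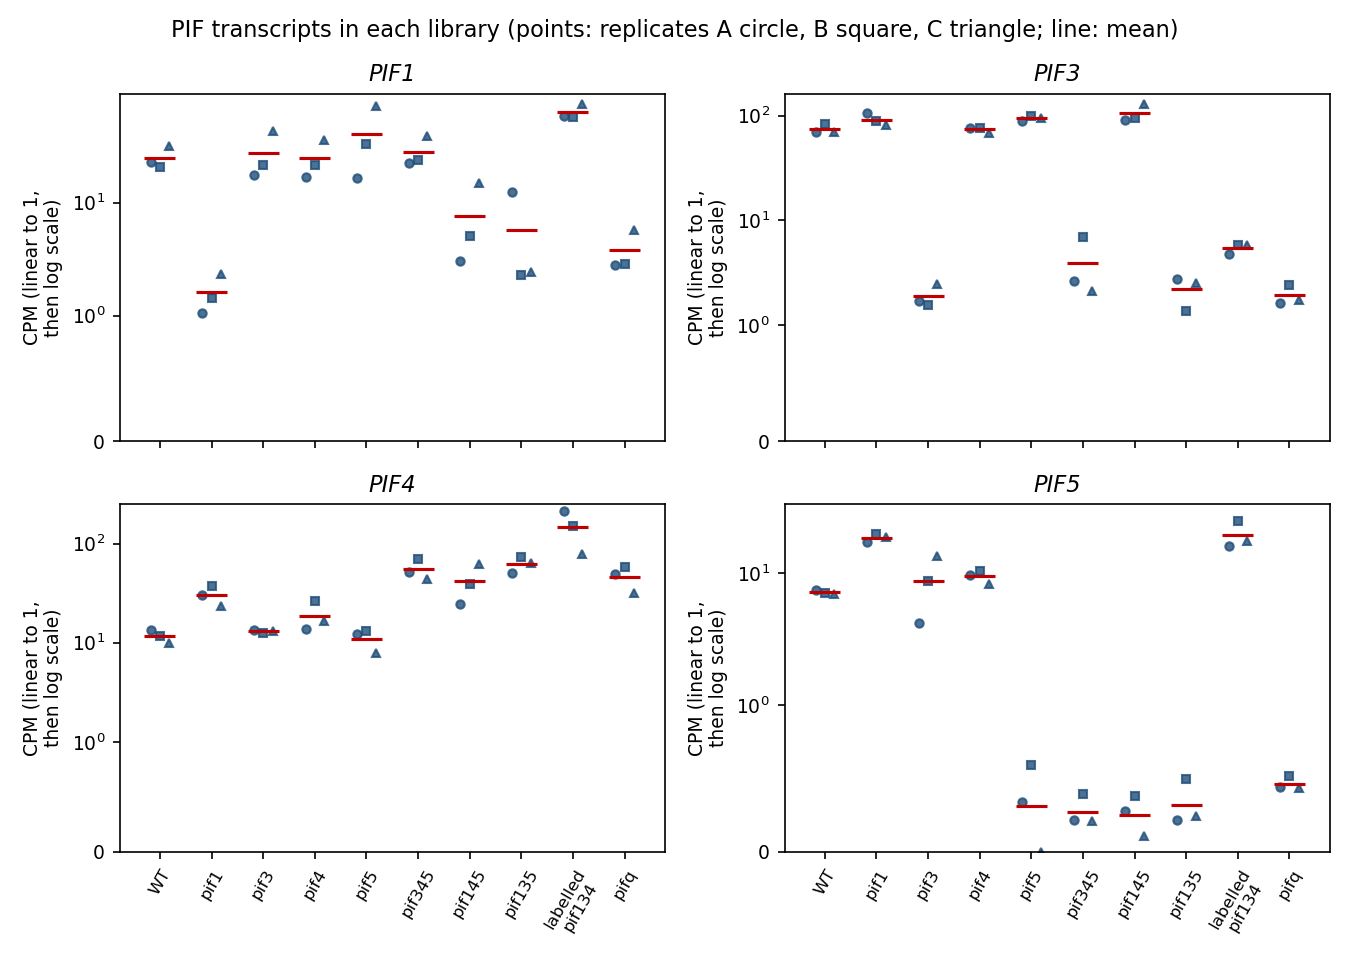
CPM of PIF1, PIF3, PIF4 and PIF5 (vertical axes, linear up to 1 and logarithmic above) in each of the 30 libraries, by genotype along the horizontal axis; points are replicates A (circle), B (square) and C (triangle) and lines are genotype means. PIF1 lies at 58.1, 56.7 and 74.5 CPM in the libraries labelled pif134, above its WT mean of 25.0 CPM.

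Genes of the photosynthetic apparatus were higher in pifq than in WT in darkness. Of 21 light-harvesting antenna genes, which encode the chlorophyll-binding proteins around the photosystems, 17 rose in pifq and none fell (19 adjusted over the list alone; median log2 fold change 3.22, adjusted p = 0.0128 with an estimated correlation). LHCB1.4 (AT2G34430, chromosome 2, 14524607 to 14525918) went from 116 CPM in WT to 7766 in pifq, a log2 fold change of 6.07 ± 0.56 (n = 3 per group, adjusted p = 1.76e-08). LHCB1.1 and LHCB1.5 rose by 4.76 ± 0.48 and 4.27 ± 0.44; these near-identical copies may share reads. Among 33 photosystem and electron transport subunits, 28 rose (32 adjusted over the list alone; median 1.84, adjusted p = 0.00892 with an estimated correlation), led by PSBW at 2.81 ± 0.40, PSAE1 at 2.49 ± 0.34 and PSAH2 at 2.41 ± 0.31. Calvin cycle genes rose in 11 of 17 cases (14 adjusted over the list alone; median 1.00, adjusted p = 0.032 with an estimated correlation), with GAPA2, a subunit of plastid glyceraldehyde-3-phosphate dehydrogenase, at 2.25 ± 0.35. Of 25 chlorophyll biosynthesis genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation). They included HEMA1, which encodes glutamyl-tRNA reductase at the entry to tetrapyrrole synthesis (1.89 ± 0.27), the chelatase activator GUN4 (2.02 ± 0.47) and the methyltransferase CHLM (1.77 ± 0.34). Of 10 carotenoid and plastid isoprenoid genes, 2 were called higher (2 adjusted over the list alone) and the list as a whole did not pass the test (adjusted p = 0.0638).

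Shade-responsive regulators fell in pifq. This list holds genes induced when plants grow in vegetation shade, and 9 of its 17 members were lower and none higher (11 adjusted over the list alone; median -1.31, adjusted p = 0.00157 with an estimated correlation). PIL1 (AT2G46970, chromosome 2, 19295431 to 19297858) dropped from 54.6 to 1.15 CPM (-5.57 ± 0.32, adjusted p = 1.54e-12). HFR1, an atypical helix-loop-helix protein that dimerises with PIFs, dropped from 69.0 to 4.86 CPM (-3.82 ± 0.32, adjusted p = 3.16e-09). PIL2, XTH15 and the homeodomain gene HB-2 changed by -3.56 ± 0.43, -2.42 ± 0.33 and -1.97 ± 0.23. Of 24 auxin genes tested, 8 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.522 with an estimated correlation), among them the auxin-response repressor IAA29 (-2.57 ± 0.46) and SAUR23 (-1.73 ± 0.34). The ethylene biosynthesis genes ACS5 (-2.73 ± 0.52) and ACS8 (-2.29 ± 0.46) were the 2 members of 17 ethylene genes called lower. Adjusted over the list alone, 1 ethylene gene was also higher. ROT3, which encodes a cytochrome P450 of brassinosteroid metabolism, was the 1 of 8 called (-1.19 ± 0.27), and of 13 gibberellin genes 1 rose and 2 fell, GA3OX1 by -1.01 ± 0.26 (1 and 3 adjusted over the list alone). Of 24 genes for cell wall loosening and cellulose synthesis, 4 fell, XTH33 by -1.75 ± 0.31 and XTH19 by -1.64 ± 0.35 (5 lower and 2 higher adjusted over the list alone), and the list did not pass the test (adjusted p = 0.0638).

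The list of photoreceptors and light-signalling regulators moved both ways in pifq, with 8 of 31 members higher and 5 lower (8 and 5 adjusted over the list alone). BBX16 (5.93 ± 0.69) and PIF7 (5.06 ± 0.55), another member of the PIF family, rose. ELIP1 and ELIP2, early light-induced proteins of the thylakoid, fell (-7.30 ± 0.39 and -4.59 ± 0.37), and so did BBX23 (-5.53 ± 0.65). ELIP1 (AT3G22840, chromosome 3, 8084405 to 8085669) went from 22.7 to 0.14 CPM, against the direction of the antenna genes. Of 10 circadian clock genes, 3 were higher, CCA1 by 1.25 ± 0.24, and the flavonoid list (8 tested) had 1 higher and 1 lower member, F3H at -1.45 ± 0.38 (1 and 3 adjusted over the list alone). Neither list passed the test as a whole (adjusted p = 0.222 and 0.606).

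Most of the seed and root hair genes tested were lower in pifq, though neither list passed with an estimated correlation. Of 24 seed storage and maturation genes, 18 fell and none rose (19 adjusted over the list alone; median -2.37, adjusted p = 0.11 with an estimated correlation), among them the oleosin genes OLEO3 (-3.90 ± 0.25) and OLEO2 (-3.83 ± 0.55). GASA2 (-5.60 ± 0.68) and GASA3 (-4.62 ± 0.54) fell as well. Among 9 root hair markers, 7 fell (8 adjusted over the list alone; median -2.51, adjusted p = 0.0891 with an estimated correlation), with the expansin EXPA7 at -3.33 ± 0.37, PRP1 at -3.64 ± 0.66 and the root hair regulator RSL4 at -2.71 ± 0.59. Of 8 stomatal lineage markers, BASL (1.47 ± 0.35) and TMM (1.45 ± 0.29) rose (3 adjusted over the list alone), and the list did not pass (adjusted p = 0.0505). Of 11 seed oil mobilisation genes 1 fell, of 8 heat shock genes none was called by edgeR, and of 8 commonly used reference genes 1, GAPC2, was higher (0.95 ± 0.28), a call that was lost without WT A, WT B or pifq A.

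Genes named as the largest rises or falls of a comparison are called genes with a mean of at least 5 CPM whose mutant replicates all lie beyond all replicates of the other genotype, the PIF genes aside. By this rule the steepest rises in pifq were in genes nearly silent in WT. AOX1D (AT1G32350, chromosome 1, 11666886 to 11668690), an alternative oxidase of mitochondria, had 5 reads over the 3 WT libraries and 4993 over the 3 pifq libraries (fitted log2 fold change 10.48 ± 1.43, adjusted p = 8.92e-06). CYP71A12 and CYP71A13, near-identical cytochrome P450 genes of the pathway to the phytoalexin camalexin, rose by 8.40 ± 1.09 and 6.91 ± 1.60, from 21 and 7 reads in WT. DIR5, AT1G26390, AT2G38823, AT4G12735, AT3G54530, AT1G26380 and AT2G04070 rose by between 6.90 and 9.10, from 4 to 138 reads in WT, and the fold changes from the fewest reads depend on the prior count. Beside ELIP1, PIL1, GASA2, GASA3 and ELIP2, the steepest falls by the same rule were AT5G04120 (-6.28), MLP31 (-4.79), PGL2 (AT3G49360, -4.72), AT1G14950 (-4.56) and NSP2 (-4.53).

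In total, 2835 genes differed between pifq and WT by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1496 higher and 1339 lower, and 2221 of them changed at least 2-fold. The larger share turned to the lower genes with scaling by total counts alone (1277 higher and 1652 lower), with the replicate block (2233 and 2364) and without WT B (1262 and 1333). Without WT A the count was 1833. This comparison crosses the 2 sets of libraries.

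**Figure D2:**
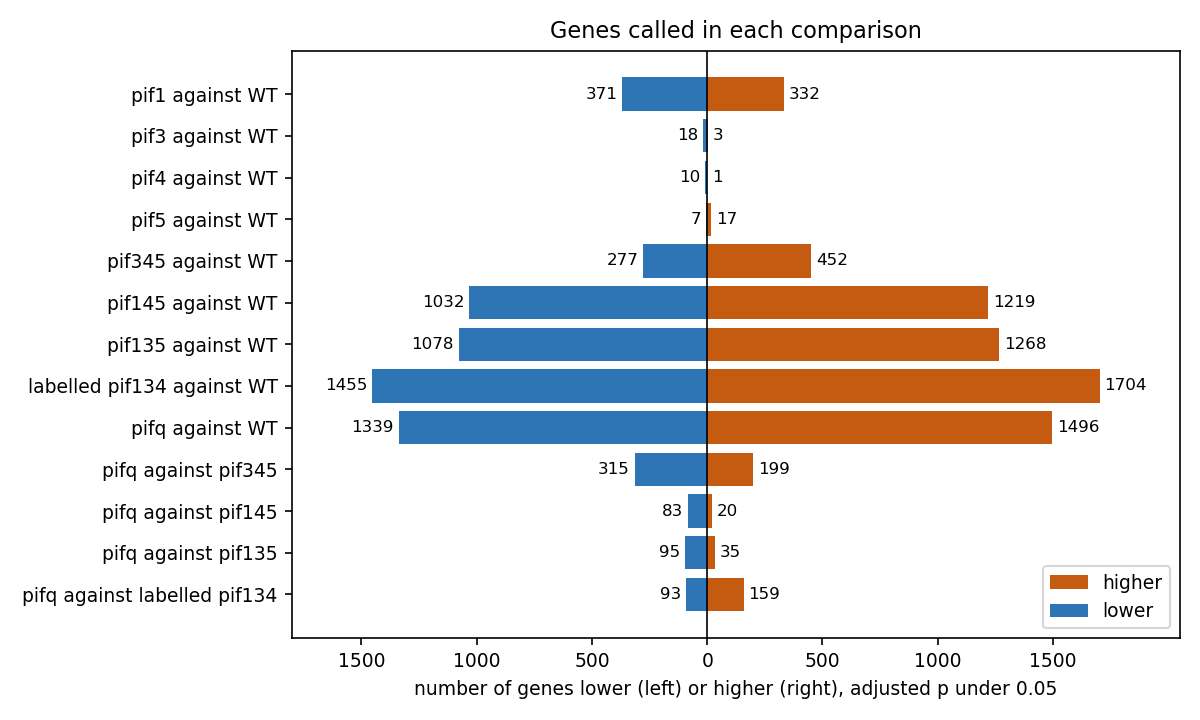
Number of genes called lower (bars to the left) and higher (bars to the right) in each of 13 comparisons at an adjusted p under 0.05, with the count at the end of each bar. Counts are from the fit without a replicate block. The single mutants pif3, pif4 and pif5 had 21, 11 and 24 calls against WT, and the triple mutants between 729 and 3159, the highest in the libraries labelled pif134, where PIF1 is not low.

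The single mutants ask what the loss of 1 factor does when the others remain. In pif1, seed transcripts were lower and antenna transcripts higher than in WT. Of 24 seed storage and maturation genes, 16 were lower in pif1 (21 adjusted over the list alone; median -3.19, adjusted p = 0.0185 with an estimated correlation), including the storage protein genes SESA5 (-6.50 ± 1.02) and CRC (-6.24 ± 0.97) and the oleosin OLEO2 (-3.88 ± 0.55). GASA2 (AT4G09610, chromosome 4, 6074770 to 6075645) had 996 reads over the WT libraries and 3 over the pif1 libraries (adjusted p = 2.21e-06). The antenna list had 16 of 21 members higher (20 adjusted over the list alone; median 1.94, adjusted p = 0.0185 with an estimated correlation), LHCB1.4 by 4.45 ± 0.52, and 14 of 33 photosystem subunits were higher (21 adjusted over the list alone; median 0.92, adjusted p = 0.0281 with an estimated correlation). Light-signalling regulators were higher in 5 of 31 cases (10 adjusted over the list alone; adjusted p = 0.0185 with an estimated correlation), BBX16 by 3.83 ± 0.68 and PIF7 by 2.96 ± 0.56. The clock list had 4 members higher and 1 lower (adjusted p = 0.0763 with an estimated correlation), LHY at 1.25 ± 0.22. PIL1 was not called (-0.45, adjusted p = 0.325), nor was any other shade-responsive regulator (none adjusted over the list alone). ESM1, an epithiospecifier modifier of glucosinolate breakdown, rose by 3.00 ± 0.41.

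In all, 703 genes differed between pif1 and WT, 332 higher and 371 lower, and 561 changed at least 2-fold. With scaling by total counts alone 324 were higher and 259 lower. With the replicate letter as a block the count was 2297, and with a block within each set of libraries 3662. It was 307 without WT A, 236 without WT C, and 455 (229 higher), 314 (166 higher) and 301 without pif1 A, B and C.

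With all libraries in one fit and no block, far fewer genes were called for the loss of PIF3, PIF4 or PIF5 alone. In pif3, 3 genes were higher and 18 lower. Among genes with a mean of at least 5 CPM, and PIF3 aside, the largest falls were STZ, a zinc-finger repressor of stress responses (AT1G27730, -2.35 ± 0.38), DIC2, a mitochondrial dicarboxylate carrier (-2.23 ± 0.41), and AT4G29780 (-2.12 ± 0.20, adjusted p = 3.34e-07). ESM1 was higher (2.04 ± 0.41, adjusted p = 0.028). The DIC2 call was lost without WT A or any pif3 replicate, and that of ESM1 without WT A, WT B, pif3 B or pif3 C. No antenna gene was called in pif3 by edgeR, and 8 of 21 were adjusted over the list alone (median 0.82, adjusted p = 0.373 with an estimated correlation). In pif4, 1 gene was higher and 10 lower. QQS, a gene linked to starch content, was the higher one (3.71 ± 0.36, adjusted p = 6.17e-07), with 14.1 CPM against 1.07 in WT. STZ (-2.41 ± 0.38), DIC2 (-2.16 ± 0.42) and AT5G35940 (-2.12 ± 0.31) were lower. The DIC2 call was lost without WT A or any pif4 replicate. Between pif3 and pif4, 9 genes were lower in both, against 0.00964 for independent lists of these sizes. Between pif1 and pif3, and pif1 and pif4, 6 and 5 were lower in both, against 0.357 and 0.199. Over all genes the covariance of fold changes was 0.0698 for pif3 and pif4, 0.133 for pif1 and pif3 and 0.134 for pif1 and pif4, where simulated unchanged groups sharing the WT libraries gave 0.0729, 0.0725 and 0.073. The simulated groups leave out the deviations that libraries of the same letter share, so these values do not settle how much the common WT contributes.

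In pif5, 17 genes were higher and 7 lower. MRD1 (AT1G53480, chromosome 1, 19963047 to 19964712) fell from 103 to 2.31 CPM (-5.47 ± 0.34, adjusted p = 2.35e-11), and AGP30, an arabinogalactan protein gene, was lower too (-3.80 ± 0.50). COPT2, a copper transporter, was lower (-2.43 ± 0.50). AT4G12735 (5.77 ± 1.06), the blue copper-binding protein gene BCB (3.43 ± 0.57) and AT2G43620 (3.05 ± 0.56) were higher. These last 4 calls were each lost without WT A or WT C, those of AT4G12735 and AT2G43620 also without WT B or pif5 C, and that of COPT2 without any pif5 replicate. STZ and DIC2 were not called (0.23 and 0.02). Of 8 heat shock genes none was called by edgeR over all genes, 6 were higher adjusted over the list alone (median 2.02, adjusted p = 0.334 with an estimated correlation), and the clock list was higher (3 members adjusted over the list alone; median 0.57, adjusted p = 0.0277 with an estimated correlation).

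The counts of calls were 21 for pif3, 11 for pif4 and 24 for pif5, with 767, 676 and 2385 genes at an unadjusted p under 0.05. With the replicate letter as a block they were 34 for pif3 and 379 for pif5, and with a block within each set of libraries, chosen after the data were seen, 52 for pif3, 18 for pif4 and 1361 for pif5. In pif5 the larger share was then lower, with 171 higher and 208 lower for the first block and 624 and 737 for the second. For pif3 the count was 10, 11 and 8 without WT A, pif3 A and pif3 B. For pif4 it was 7 without WT A. For pif5 it was 6, 15 and 6 without WT A, B and C, and 48, 13 and 8 without pif5 A, B and C, and scaling by total counts alone gave 43 higher and 4 lower.

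The triple mutants ask what a single remaining factor can maintain. In pif345, which keeps PIF1, the seed list was not low, with 2 of 24 members higher and 1 lower (2 higher and 2 lower adjusted over the list alone; median 0.51), the lower one being OLEO3 (-1.73 ± 0.23). The antenna list had 15 of 21 members higher (17 adjusted over the list alone; median 1.75, adjusted p = 0.0648 with an estimated correlation), LHCB1.4 by 3.57 ± 0.50. Of the photosystem subunits 8 of 33 were higher (19 adjusted over the list alone; median 0.81, adjusted p = 0.112 with an estimated correlation). Of the shade-responsive regulators, 2 of 17 were lower (3 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation), among them HFR1 (-1.55 ± 0.29). The root hair list had 6 of 9 members lower (8 adjusted over the list alone; median -1.76, adjusted p = 0.112 with an estimated correlation). Heat shock genes were higher in 4 of 8 cases (6 adjusted over the list alone; median 2.08, adjusted p = 0.237 with an estimated correlation). The largest rises were AOX1D (9.10, adjusted p = 0.000326), CYP71A13 (8.11 ± 1.62, lost without pif345 B), from 5 and 7 reads in WT, and CYP71B22, with 3 reads in WT and 676 in pif345. The largest falls by the same rule, PIF3 and PIF5 aside, were PGL2 (-3.55 ± 0.28), AGP30 (-3.52 ± 0.50) and COPT2 (-2.79 ± 0.51). In total 729 genes differed from WT, 452 higher and 277 lower, or 593 and 149 with scaling by total counts alone and 880 and 922 with the replicate block. The count was 307 and 287 without WT A and C, and 476, 255 and 438 without pif345 A, B and C.

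In pif145, which keeps PIF3, and in pif135, which keeps PIF4, the antenna list passed the test with an estimated correlation and the seed list did not. The antenna list had 17 and 18 of 21 members higher (19 and 19 adjusted over the list alone; medians 2.77 and 2.94, adjusted p = 0.0145 and 0.0137 with an estimated correlation). LHCB1.4 rose by 5.61 ± 0.55 and 5.74 ± 0.55. Photosystem subunits were higher in 25 and 27 of 33 cases (29 and 29 adjusted over the list alone; medians 1.59 and 1.70, adjusted p = 0.0145 and 0.0137 with an estimated correlation). Of the seed genes, 15 fell and 1 rose in pif145 (18 and 1 adjusted over the list alone; median -2.22, adjusted p = 0.0726 with an estimated correlation), and 19 fell in pif135 (20 adjusted over the list alone; median -2.95, adjusted p = 0.0593 with an estimated correlation). GASA2 changed by -6.01 ± 0.70 and -6.90 ± 0.74. Of 17 shade-responsive regulators, 6 and 7 were lower (7 and 7 adjusted over the list alone; adjusted p = 0.0145 and 0.0593 with an estimated correlation), with PIL1 at -2.69 ± 0.27 and -2.02 ± 0.26. ELIP1 went to 8.20 CPM in pif145 (-1.47 ± 0.27) and to 0.17 CPM in pif135 (-7.05 ± 0.38). MRD1 was the largest fall in pif145 (-6.02 ± 0.35), and AT5G35660 (-5.51 ± 0.79) and AT3G05260 (-5.46 ± 0.75) followed in pif145 and pif135. AOX1D rose by 9.74 and 8.88 (adjusted p = 3.91e-05 and 7.66e-05), with 16.4, 14.3 and 108.0 CPM in pif145 A, B and C and 73.7, 2.47 and 0.77 in pif135 A, B and C. AT1G26390 rose in both, by 8.15 ± 1.38 and 7.27 ± 1.35, the latter call lost without pif135 A. DIR5 rose by 8.02 ± 1.33 in pif145 and AT2G38823 by 6.98 ± 1.33 in pif135 (14.8 CPM in A and 0.32 in C), all from 4 to 21 reads in WT.

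In pif145, 2251 genes differed from WT, 1219 higher and 1032 lower, and in pif135, 2346, with 1268 higher and 1078 lower. For pif145 the count was 1369, 1290 and 877 without WT A, WT C and pif145 C, and 974 with only these 2 genotypes in the fit. The lower genes outnumbered the higher ones with scaling by total counts alone (1055 higher and 1137 lower) and without WT B (912 and 934). For pif135 the count was 1392, 1311 (630 higher and 681 lower) and 1291 without WT A, WT C and pif135 C, and without WT B 1056 were higher and 1095 lower.

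The libraries labelled pif134, in which PIF1 is not low, had the most calls against WT, 3159, with 1704 higher and 1455 lower, or 1368 and 1980 with scaling by total counts alone. Without pif134 B the count was 2008. All 9 root hair markers were lower (9 adjusted over the list alone; median -4.93, adjusted p = 0.0643 with an estimated correlation), including EXPA7 (-5.41 ± 0.45) and RSL4 (-4.13 ± 0.67). Antenna genes were higher in 17 of 21 cases (17 adjusted over the list alone; median 2.19, adjusted p = 0.0775 with an estimated correlation), and photosystem subunits in 23 of 33 (26 adjusted over the list alone; adjusted p = 0.0775 with an estimated correlation). Seed genes were lower in 18 of 24 cases (19 adjusted over the list alone; median -2.96, adjusted p = 0.0895 with an estimated correlation), as in pif1 and unlike in pif345, although PIF1 transcript was present. PIL1 and HFR1 were lower (-1.74 ± 0.26 and -2.08 ± 0.30), and 5 of 17 shade-responsive regulators were lower (5 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation). AOX1D (11.42 ± 1.46) and DIR5 (10.34 ± 1.39) rose most, from 5 and 8 reads in WT, with CYP71B22 between them (3 reads in WT and 2624 in these libraries). AGP30 (-7.70 ± 0.68), GASA2 (-7.08 ± 0.80) and MLP31 (-6.82 ± 0.87) fell most.

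Fold changes against WT correlated across genes between the triple mutants, with r from 0.68 for pif345 and pif135 to 0.89 for pif145 and pif135, where unchanged groups sharing these WT libraries gave 0.49 on average. Genes are not independent replicates here. The covariance exceeded the simulated one by 0.388 for pif345 and pif135 and by 0.622 for pif145 and pif135. In pif145 and pif135, 824 genes were higher in both and 696 lower in both, against 82.7 and 59.6 for independent lists. With pifq, the libraries labelled pif134 shared 1086 higher and 865 lower genes, against 136 and 104. With 3 WT libraries the controls could not be split, and part of these overlaps may come from the shared WT, or from the set the mutants share.

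**Figure D3:**
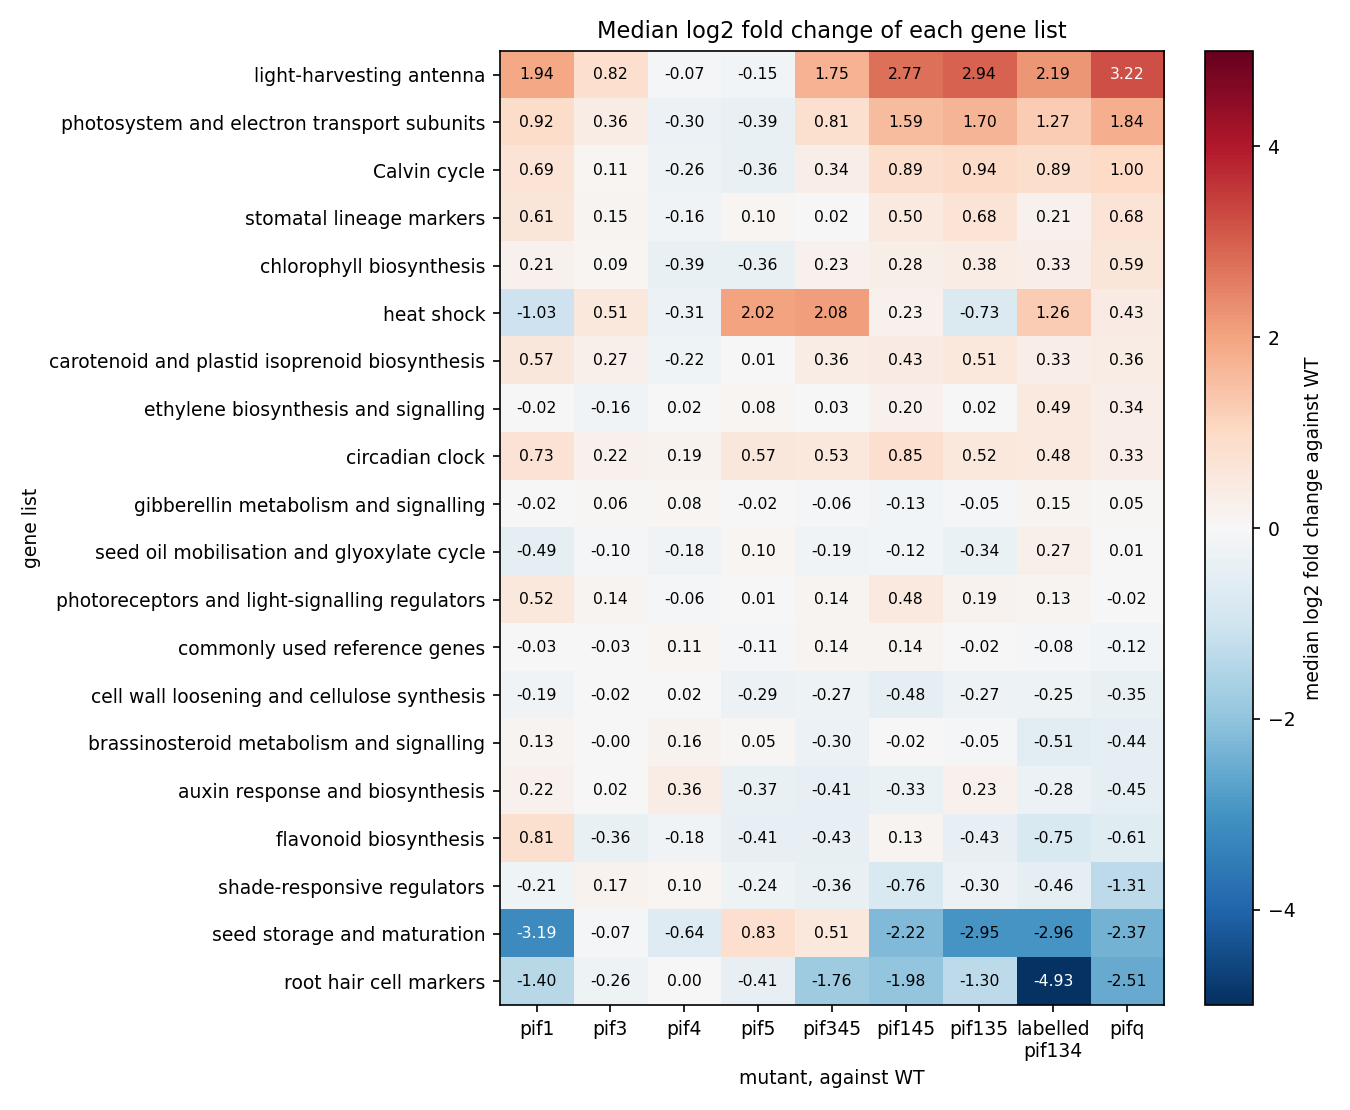
Median log2 fold change against WT (number and color in each cell, red higher and blue lower) of the 20 gene lists (vertical axis) in the 9 mutants (horizontal axis). The antenna list has medians of 1.94 in pif1, 1.75 in pif345 and 3.22 in pifq, and the seed list -3.19 in pif1, 0.51 in pif345 and -2.37 in pifq.

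Comparing pifq with each triple mutant asks what the last factor does when the other 3 are gone, within 1 set of libraries. PIL1 was lower in pifq than in every triple mutant, with log2 fold changes of -5.21 ± 0.31 against pif345, -2.87 ± 0.29 against pif145, -3.55 ± 0.30 against pif135 and -3.83 ± 0.30 against the libraries labelled pif134. HFR1 was lower as well (log2 fold changes from -2.27 against pif345 to -1.74 against the libraries labelled pif134, SE 0.30 in each), and the calls against pif145, pif135 and the libraries labelled pif134 were lost with only the compared genotypes in the fit. The shade-responsive list was lower in all 4 comparisons, with 6, 3, 6 and 7 of 17 members called (8, 7, 9 and 7 adjusted over the list alone) and adjusted p = 0.00243, 0.00408, 0.00138 and 0.000387 with an estimated correlation. XTH15 was lower than in pif345 (-2.50 ± 0.33) and in the libraries labelled pif134 (-2.79 ± 0.34). OLEO3 was lower than in pif345, pif145 and the libraries labelled pif134, at -2.17 ± 0.24, -1.84 ± 0.23 and -1.66 ± 0.23.

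Against pif345, where the last factor is PIF1, 15 of 24 seed genes were lower in pifq (22 lower and 1 higher adjusted over the list alone; median -2.84, adjusted p = 0.0146 with an estimated correlation), OLEO2 among them (-3.81 ± 0.55). ELIP1 (-6.41 ± 0.39), AT5G04120 (-5.55 ± 0.61) and PIL1 fell most, and AT1G04660 (2.98 ± 0.35), COPT2 (2.65 ± 0.52) and AT4G28780 (2.50 ± 0.29) rose most. The antenna list was higher in 13 of 21 cases (16 adjusted over the list alone; median 1.26, adjusted p = 0.0591 with an estimated correlation), LHCB1.4 by 2.49 ± 0.47. Photosystem subunits were higher in 9 of 33 (28 adjusted over the list alone; median 0.93, adjusted p = 0.0146 with an estimated correlation). In all 514 genes differed, 199 higher and 315 lower, or 91 and 548 with scaling by total counts alone, and 924 with the replicate letter as a block. The count was 329 and 295 without pif345 A and C and 251 without pifq B.

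Fewer genes separated pifq from the other triple mutants. Against pif145, where the last factor is PIF3, ELIP1 (-5.83 ± 0.39), ELIP2 (-4.08 ± 0.36) and PGL2 (-3.67 ± 0.30) were lower, and MRD1 (6.38 ± 0.35), AT4G12870 (2.36 ± 0.30) and AT3G05730 (1.99 ± 0.32, lost with only these 2 genotypes in the fit) were higher. Light-signalling regulators were lower in 5 of 31 cases (5 adjusted over the list alone; adjusted p = 0.00828 with an estimated correlation), and no antenna or photosystem gene was called by edgeR (medians 0.26 and 0.24; none adjusted over either list alone). Of 103 genes 20 were higher and 83 lower, with 180 under the replicate block, 48, 67 and 53 without pifq A, B and C, and 17 with only these 2 genotypes in the fit. Against pif135, where the last factor is PIF4, MRD1 (4.73 ± 0.32) was higher, and the auxin list had 4 of 24 members lower (13 lower and 1 higher adjusted over the list alone; median -0.70, adjusted p = 0.17 with an estimated correlation). MRN1 (-2.48 ± 0.46) and AT1G45015 (-2.24 ± 0.38) were lower and AT2G43620 (2.48 ± 0.53) and AT4G36430 (2.36 ± 0.57) higher, all 4 lost without pifq A. The calls of MRN1, AT2G43620 and AT4G36430 were also lost without pif135 B, and the latter 2 without pif135 C, that of AT4G36430 without pifq B or C as well. Here 130 genes differed, 35 higher and 95 lower, or 22 and 111 with scaling by total counts alone, and 384 under the replicate block. This count and its direction rest on single libraries, with 530 (343 higher and 187 lower), 47 and 19 without pif135 A, B and C, 12 and 74 without pifq A and B, and 3 with only these 2 genotypes in the fit.

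Against the libraries labelled pif134, pifq was lower in PIF5 (-5.37 ± 0.52) and also in PIF1 (-4.06 ± 0.64, adjusted p = 0.000383), so this difference does not isolate PIF5. QQS (6.67 ± 0.43), AIR1 (4.21 ± 0.38) and AT5G46890 (4.86 ± 0.90, lost without pifq B) were higher in pifq, and AT5G04120 (-4.78 ± 0.61) and PGL2 (-4.61 ± 0.31) lower. CYP71B22 was also lower (-3.85 ± 0.98, adjusted p = 0.0416), a call lost with DESeq2 and without pif134 A, pif134 B, pifq B or pifq C. The root hair list was higher in 2 of 9 cases (7 adjusted over the list alone; median 2.28, adjusted p = 0.0651 with an estimated correlation). Of 252 genes 159 were higher and 93 lower, with 423 under the replicate block, 155, 131 and 134 without pif134 A, pifq B and pifq C, and 91 with only these 2 genotypes in the fit.

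Whether the loss of a factor had a different effect in WT and in the matching triple mutant was tested as an interaction. For PIF1, 122 genes differed, 26 with a higher and 96 with a lower response in the triple mutant background, led by ELIP1, PIL1 and ELIP2. Loss of PIF1 changed PIL1 by -0.45 in WT and by -5.21 in pif345, and ELIP1 by 0.87 (adjusted p = 0.0552) and -6.41. For PIF3 the count was 41, 14 higher and 27 lower, with MRD1, ELIP1 and PGL2 leading. For PIF4 it was 98, 26 higher and 72 lower, with PIL1 changed by 0.38 in WT and -3.55 in pif135, beside MRD1 and QQS. For PIF5, measured through the libraries labelled pif134 in which PIF1 is not low, it was 247, 161 higher and 86 lower. Scaling by total counts alone gave splits of 9 and 227, 10 and 35, 23 and 119, and 126 and 125, and the replicate block gave counts of 971, 68, 483 and 514. With only the compared groups in the fit the PIF5 split was 115 and 131.

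Between 1 and 11 single libraries moved each of these interaction counts by more than 1.5 times. For PIF1 the count was 74, 197 and 54 without WT A, B and C, 62 and 67 without pif1 A and B, 75, 79 and 73 without pif345 A, B and C, and 73, 74 and 232 without pifq A, B and C. For PIF3 it was 22, 21 and 23 without WT A, B and C, 24, 19 and 18 without pif3 A, B and C, 27 without pif145 A, and 18, 22 and 26 without pifq A, B and C. For PIF4 it was 51 and 16 without WT B and C, 15 and 59 without pif4 B and C, 323 (190 higher and 133 lower) and 21 without pif135 A and C, and 8 without pifq A. For PIF5 it was 154 without pifq B.

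Tests among the mutants as a group gave 1651 genes that differed among the 4 triple mutants and 838 among the 4 single mutants. Among the triple mutants PIF3, MRD1, ELIP1, QQS and PIF5 had the smallest adjusted p. MRD1 stood at 33.9, 1.59, 4.99 and 115 CPM in pif345, pif145, pif135 and the libraries labelled pif134, and QQS at 52.2, 17.45, 111 and 0.50 CPM. Among pif345, pif145 and pif135 alone 499 genes differed, so the larger count rests partly on the libraries labelled pif134, in which PIF1 is not low. Among the single mutants MRD1, PIF3, QQS, AT3G43715 and ORA47 led. ORA47, a jasmonate-responsive regulator, held 0.51, 0.14 and 0.21 CPM in pif1, pif3 and pif4 and 3.34 in pif5, beside 3.46 in WT. The replicate block gave 2755 and 1912, and the single mutant count was 544 without pif1 C and 542 without pif5 B.

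**Figure D4:**
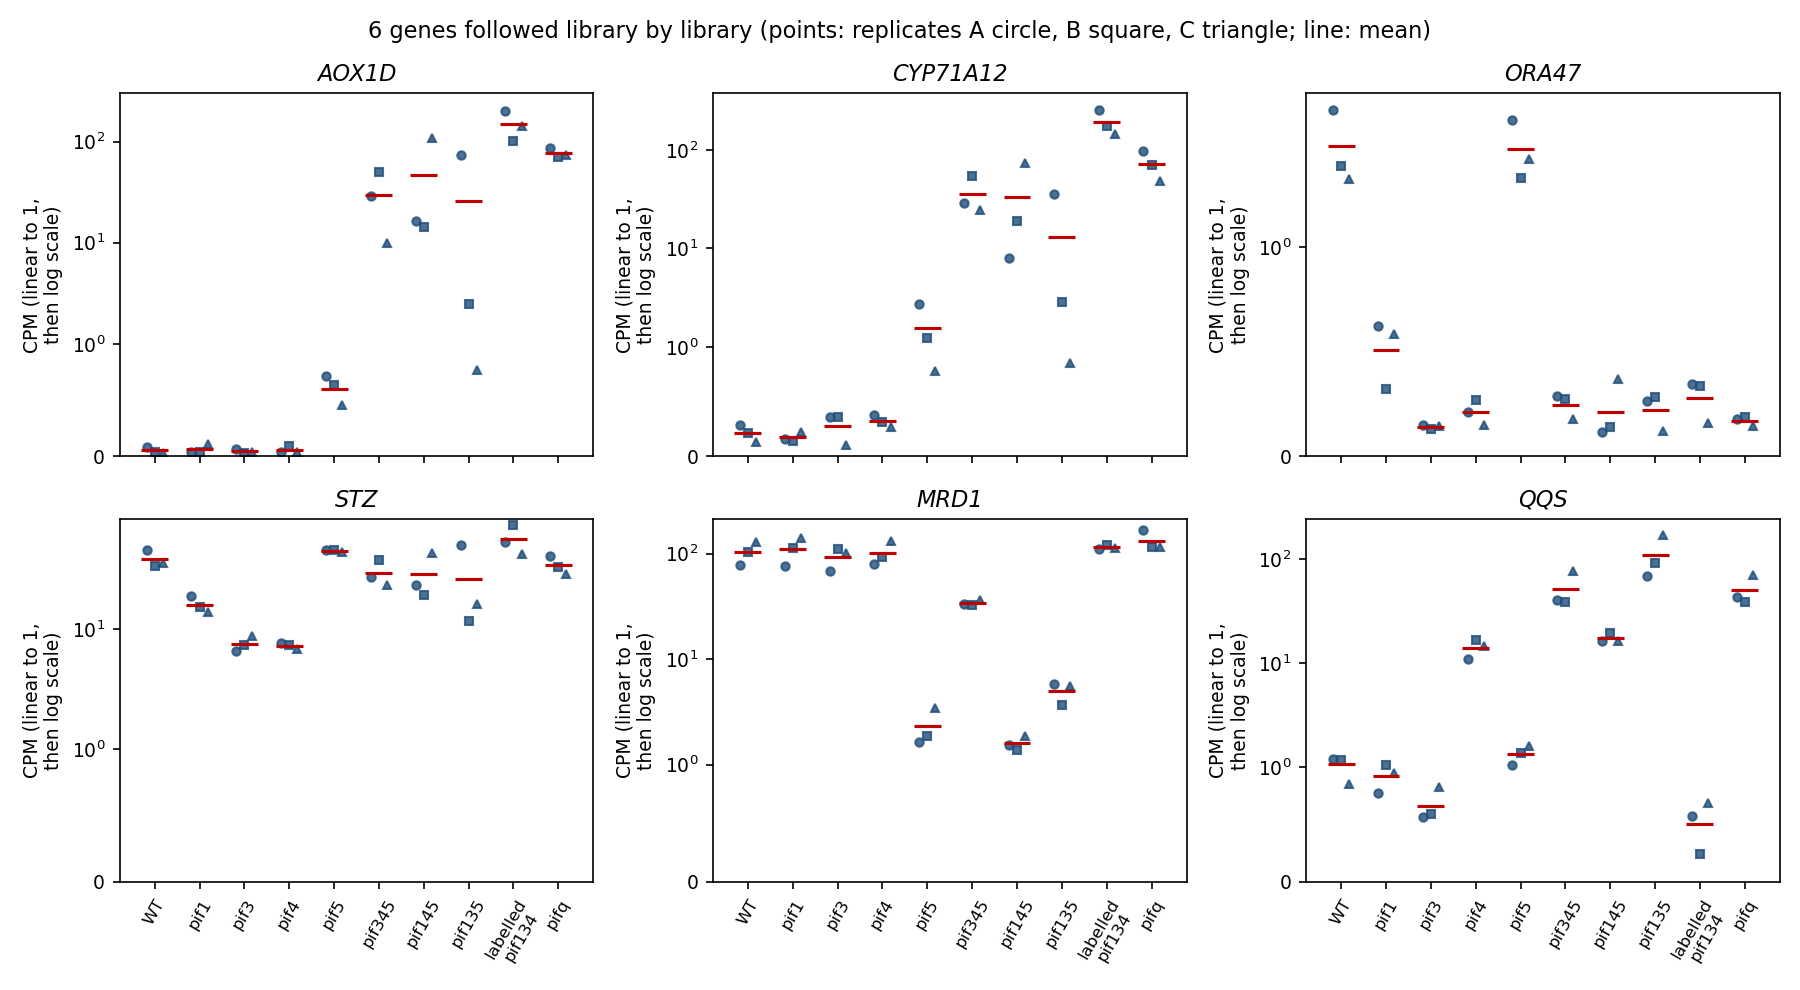
CPM of AOX1D, CYP71A12, ORA47, STZ, MRD1 and QQS (vertical axes, linear up to 1 and logarithmic above) in each library, by genotype along the horizontal axis; points are replicates A (circle), B (square) and C (triangle) and lines are means. AOX1D averages 0.05 CPM in WT and 77.2 in pifq, and MRD1 averages 103 CPM in WT and 2.31 in pif5.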

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

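The tests weighed here were chosen after the result was seen, except the handling or growth test and the wider defence test. The results in this part are differences between the effect of losing a PIF in WT and in the triple mutant background, found by an interaction test.

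For PIF1, 122 genes responded differently in the 2 backgrounds. The interaction was -7.27 ± 0.47 for ELIP1, whose response was 0.87 in WT (adjusted p = 0.0552) and -6.41 in the triple background, -4.76 for PIL1 (-0.45 and -5.21) and -4.28 for ELIP2 (1.05, adjusted p = 0.0588, and -3.23). For PIF3, 41 genes differed, with 6.52 for MRD1 (-0.15 and 6.38), -4.94 for ELIP1 (-0.88 and -5.83) and -3.64 for PGL2 (-0.03 and -3.67). For PIF4, 98 genes differed, with 4.76 for MRD1 (-0.03 and 4.73), -4.84 for QQS (3.71 and -1.12, adjusted p = 0.0948) and -3.92 for PIL1 (0.38 and -3.55). For PIF5, 247 genes differed, with 5.67 for MRD1 (-5.47 and 0.21), -4.73 for PGL2 (0.12 and -4.61) and 6.35 for QQS (0.32 and 6.67), measured through libraries in which PIF1 is not low. MRD1 and QQS did not follow the PIF genotype over the 10 genotypes, with MRD1 between 93.1 and 132 CPM in WT, pif1, pif3, pif4, the libraries labelled pif134 and pifq, at 33.9 in pif345, and at 2.31, 1.59 and 4.99 CPM in pif5, pif145 and pif135.

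Other ways to split the same libraries gave as many calls for 3, 3, 4 and 3 of 25 splits in the PIF1, PIF3, PIF4 and PIF5 interactions, the real one included. The highest other splits called 862, 349, 2048 and 3243 genes. They mix genotypes and set WT and single mutant libraries against triple mutant and pifq libraries, whose differences then enter the contrast, so these splits do not decide whether chance gives the real counts. Among the triple mutants 2 of 40 splits gave as many genes (1651, highest other 1827), a share that does not exclude chance, but these splits also mix genotypes and part the replicate letters. Among the single mutants 1 of 40 did (838, highest other 433), which excludes chance only as far as splits of this kind can, since they too mix genotypes and part the replicate letters. For the 13 comparisons of 3 libraries with 3, 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. The highest other split called 0 genes in each of them except pifq against pif145 (1, real 103) and against pif134 (6, real 252).

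The PIF1 transcript was not low in the libraries labelled pif134 (log2 fold change 1.33 ± 0.57). Libraries of pif3 or pif345 under this label are argued against by the seed list, whose median was -2.96 there, 0.51 in pif345 and -0.07 in pif3. The list did not pass in the libraries labelled pif134 with an estimated correlation. For pif345 PIF5 argues against it as well, with 16.0 to 24.9 CPM in the libraries labelled pif134 and 0.21 to 0.39 in pif345. Reads of the 3′ end from a transcript made downstream of an insertion may explain the 1.33, but counts per gene hold no read positions, so this cannot be told apart from an intact PIF1 gene. With the same protocol PIF1 held 1.05 to 2.34 CPM in pif1 and 2.79 to 5.69 in pifq. It was less even in pif145 (3.04, 5.07 and 14.9 CPM in A, B and C) and pif135 (12.4, 2.28 and 2.43). All of these values lay below every WT library (20.7 to 31.8 CPM), so these lines give no example of such a transcript at this level. Whether its level can differ this much between lines with the same lesion was not tested. A line of another genotype also stays open, untested.

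STZ, DIC2, AT4G29780 and ORA47 were lower than in WT in pif1, pif3 and pif4, and all but STZ also in the triple mutants and pifq. Loss of PIF3 or PIF4 as the whole cause is argued against for STZ and DIC2 by pif1, where both PIFs are intact. There all 4 genes were lower than in WT (ORA47 -2.75 ± 0.41, STZ -1.26 ± 0.36), which restates the pattern. Against pif5, a comparison without the WT libraries, 3 of the 4 were lower in pif1 (ORA47 -2.71 ± 0.41, DIC2 -1.58 ± 0.41, STZ -1.49 ± 0.36), while AT4G29780 was not (0.00 ± 0.20). ORA47 was named from the test among the single mutants, which already sets pif1 against pif5, so it adds no separate evidence. In pif5 STZ, DIC2 and ORA47 were already known to lie near WT (0.23, 0.02 and -0.04). The comparison with pif5 therefore largely repeats that with WT and is no independent test. What it adds is that STZ and DIC2 were lower in every pif1 library than in every pif5 library, as they were than in every WT library. The rapid wound and touch response list, tried first as the test, did not decide (median -0.51 in pif1, adjusted p = 0.437 with an estimated correlation). The SE of this median, 0.158, comes from the spread over its 23 genes and takes them as independent, which the estimated correlation does not. A part of the falls in pif3 and pif4 from these losses stays open. A difference in handling or growth between the WT and pif5 libraries and the others may be involved: the same list had a median below -0.5 in 3 of the 8 mutants other than pif5, while 8 of its 23 members were higher and 2 lower in the libraries labelled pif134, which leaves it open. A role of the PIFs in these genes stays open too.

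AOX1D and 9 other genes had the largest rises in pifq among called genes with a mean of at least 5 CPM and no overlap of replicates. Of the 10 genes, 4 were called among the triple mutants and 1 in pif5 against WT, tests that each stay within 1 set. As the whole cause, a difference between the 2 sets that acted alike on all libraries of a set is argued against for these called genes. The test among the triple mutants includes the libraries labelled pif134, in which PIF1 is not low. A difference between the sets that acted unevenly on their libraries stays open. A response that varies between replicates fits pif135, where the highest replicate exceeded the lowest 45.4 times (median of the 10 genes), against 8.45 in pif145, 4.41 in pif345, 1.89 in the libraries labelled pif134 and 1.69 in pifq. A wider defence response is a candidate explanation for the rise in pifq, with 9 members of the camalexin and defence list higher. Whether the loss of PIFs or a growth condition shared by the triple mutants and pifq started it stays open.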

How the results depend on the processing

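Chosen after the data were seen were the replicate block within 2 sets, the fit without the libraries labelled pif134 and the test among the other triple mutants. No named gene or list that was called in the main fit or under an alternative reversed its direction between them. A change of sign in results called in neither was not counted. The side with more calls did turn in some: with total counts alone for pif1 (324 higher, 259 lower), pif145 (1055, 1137), pif134 (1368, 1980) and pifq (1277, 1652), with the replicate block for pif5 (171, 208), pif345 (880, 922) and pifq (2233, 2364), with the block within 2 sets for pif5 (624, 737), and with only the compared groups for the PIF5 interaction (115, 131). It also turned without pif1 A (229, 226) or B (166, 148) for pif1, without WT B for pif145 (912, 934), pif135 (1056, 1095) and pifq (1262, 1333), without WT C for pif135 (630, 681), and without pif135 A for pifq against pif135 (343, 187) and the PIF4 interaction (190, 133). RLE scaling, no filter on low counts and the fit without the libraries labelled pif134 left each count of genes within 1.5 times. For named genes, 818 results kept their side of the threshold with RLE scaling (6 lost), 794 with total counts alone (22 lost), 814 with no filter (8 lost), 795 with DESeq2 (30 gained, 1 lost), 779 with the replicate block (47 gained) and 752 with only the compared groups (48 lost). With 1 library left out, 4692 kept their side and 370 lost their call. For the counts below the cause was not tested, except that a stricter adjusted p lowers the number of calls by construction. Fewer genes tested leave fewer genes that can be called, and fewer libraries in the fit gave both lower and higher counts.

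With DESeq2 the counts were 1277 for pif1, 45 for pif3, 23 for pif4, 199 for pif5, 1099 for pif345, 175 and 367 for pifq against pif145 and pif135, 448, 72, 360 and 439 for the PIF1, PIF3, PIF4 and PIF5 interactions, and 1496 among the single mutants. Of these, DESeq2 split pif3 into 12 higher and 33 lower, pif5 into 108 and 91, pifq against pif145 into 54 and 121 and against pif135 into 153 and 214, the PIF1 interaction into 204 and 244 and the PIF4 interaction into 154 and 206. At an adjusted p under 0.01 they were 236 for pif1, 11 for pif3, 8 for pif5, 264 for pif345, 985 for pif145, 1000 for pif135, 1840 for pif134, 1494 for pifq, 263, 41, 27 and 136 for pifq against pif345, pif145, pif135 and pif134, 47, 13, 11 and 124 for the interactions, 850 among the triple and 432 among the single mutants. With a mean CPM of at least 5 they were 9 for pif3, 6 for pif4, 11 for pif5, 367 for pif345, 1956 for pif134, 1782 for pifq, 329, 64, 85 and 148 for pifq against the triple mutants, 72, 19 and 135 for the PIF1, PIF3 and PIF5 interactions, 953 among the triple and 491 among the single mutants.

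With only the compared groups in the fit the counts rose to 68 for pif5 and 222 for the PIF1 interaction, and were 974 for pif145, 17, 3 and 91 for pifq against pif145, pif135 and pif134, 13 and 16 for the PIF3 and PIF4 interactions, and 805 among the triple mutants. Total counts alone gave 47 for pif5 and 236 for the PIF1 interaction. The replicate block gave 2297 for pif1, 34 for pif3, 379 for pif5, 1802 for pif345, 4048 for pif145, 4133 for pif135, 4597 for pifq, 924, 180, 384 and 423 for pifq against the triple mutants, 971, 68, 483 and 514 for the interactions, 2755 among the triple and 1912 among the single mutants. The block within 2 sets gave 3662 for pif1, 52 for pif3, 18 for pif4, 1361 for pif5, 1934, 394, 1213 and 626 for pifq against the triple mutants, 2508, 149, 1309 and 939 for the interactions, 4517 among the triple and 3598 among the single mutants. Among pif345, pif145 and pif135 alone 499 genes differed.

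Leaving out 1 library at a time gave ranges of 236 to 800 for pif1, 8 to 22 for pif3, 7 to 11 for pif4, 6 to 48 for pif5, 255 to 715 for pif345, 877 to 2611 for pif145, 1291 to 2151 for pif135, 2008 to 3579 for pif134 and 1833 to 2595 for pifq. They were 251 to 480, 48 to 96, 12 to 530 and 131 to 296 for pifq against pif345, pif145, pif135 and pif134, 54 to 232, 18 to 36, 8 to 323 and 154 to 346 for the interactions, 1114 to 1911 among the triple and 542 to 961 among the single mutants.

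Of 260 list tests 79 lost their call with the estimated correlation, and 259 and 257 stayed on their side of the threshold with RLE scaling and total counts alone. With no filter 3 lost and 4 gained a call, with the replicate block 4 lost one, and with the block within 2 sets, which could be run only for comparisons within a set, 3 lost and 2 gained one. Alternatives that the columns could not give, and so were not run, are separate technical runs, other sets of WT columns and a split of the WT libraries.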

Other observations

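Both lists in this part were written after the main results were seen, and the handling or growth test and the wider defence test with them were set down before their own results.

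Defence genes beyond the named rises were higher in pifq, pif345 and the libraries labelled pif134, while the list did not pass in pif145 and pif135 with an estimated correlation. Of 14 camalexin and defence genes tested, 9 were higher in pifq against WT (median log2 fold change 2.26, or 1.58 with genes listed at 0 at their bound; adjusted p = 0.00479 with an estimated correlation). They included PAD3 (8.10), which acts in the last steps of camalexin synthesis, CYP79B2 (2.71), CYP81F2 (4.66), GSTF6 (5.05), the immune regulators EDS1 (1.80) and PAD4 (1.37), the salicylate synthesis gene ICS1 (0.93) and FRK1 (3.84). CYP82C2 was listed at 0 in WT. In the libraries labelled pif134, 9 were higher and 1 lower (median 2.83, adjusted p = 0.0126 with an estimated correlation), and in pif345, pif145 and pif135, 4, 4 and 3 were higher (medians 1.49, 1.60 and 1.21, or 1.05, 1.31 and 1.07 with bounds; adjusted p = 0.0139, 0.0592 and 0.247). In the single mutants the medians lay between 0 and 0.23, or at 0.37, -0.04, 0.44 and 0.38 with bounds in pif1, pif3, pif4 and pif5, and PR1 in pif1 was the only member called. Within 1 set, the list was higher in pifq than in pif145 and pif135, though no member was called (medians 0.81 and 1.25, adjusted p = 0.041 and 0.00824 with an estimated correlation). Against pif345 and the libraries labelled pif134 it did not pass (medians 0.72 and 0.14, adjusted p = 0.176 and 0.883).

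Rapid wound and touch response genes, which respond within minutes to handling, were lower in pif3 and pif4. Of 23 genes tested, the median was -1.12 in pif3 and -1.17 in pif4 (adjusted p = 0.000114 and 0.000294 with an estimated correlation). ERF109 (-6.14 and -5.42) was called in both, WRKY46 and JAZ1 (-1.73) in pif3. The medians were -0.51 in pif1, -0.27 in pif5, -0.34 in pif345, -0.35 in pif145, -0.31 in pif135, 0.01 in the libraries labelled pif134 and -0.41 in pifq. In the libraries labelled pif134, 8 members were called higher and 2 lower, and in pif345, pif145 and pif135 1 was higher in each and 2, 3 and 3 were lower. In pifq the members moved apart, with TCH3 (3.04), ZAT12 (1.69), MYB15 (1.72) and SZF2 (1.21) higher and ERF109 (-6.60), JAZ7 (-2.16), JAZ8 (-3.67), JAZ1 (-1.28) and WRKY46 (-1.21) lower.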
